A study of Mus musculus with 2 samples.

How the data were processed

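RNA was measured by sequencing of total RNA on an Illumina HiSeq instrument, per the labels, in 1 library of p65 wild-type and 1 library of p65-null immortalised mouse embryonic fibroblasts. Genotype was taken from the labels, and each column of the deposited table was matched to its library by name. The submitters' processing notes name bcl2fastq 2.16, STAR 2.4, HOMER, edgeR and the build mm10, without giving their roles. The counting rule, its use of strand, the annotation release and any filter are not given in the sources used here.

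The deposited table holds 16881 RefSeq transcripts with 1 value per library. Although it is named as raw counts, its values are a scaled signal, as deposited: they are not whole numbers, and both columns sum to the same total, 18117934 for wild-type and 18117930 for p65-null. Ratios with counting intervals had been planned on raw counts, so the unit differs from the one assumed before the data were examined. Within a column, the values were whole multiples of 1 step, 0.436 in the wild-type and 0.587 in the p65-null column. All 15555 wild-type and 15479 p65-null values low enough to check came out whole (100%), within a tolerance of 0.0055 units. Even multiples were in excess, at 72.8% and 75.7% of values of 1 to 20 steps, so that 1 fragment was taken as 2 steps, a mate of a pair counting for 1 step. Dividing by the step gave 41588951 and 30882788 reads, or 20794476 and 15441394 fragments, and the common column total matches the mean of these fragment totals. No count test was run on the recovered reads, since 1 library per genotype leaves no residual degree of freedom.

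Transcripts were matched to gene symbols and GRCm38 coordinates through a RefSeq gene table (16743 matched) and otherwise through GENCODE M21 (83 matched). The other 55 transcripts had no match, and they took 3.13% of the wild-type and 3.84% of the p65-null signal, of which transcript NR_046233 alone took 3.03% and 3.75%. A further 10 entries repeated a symbol and were kept under their transcript. The table held 1023 transcripts at 0 in the wild-type and 1203 at 0 in the p65-null column. Mitochondrial transcripts could not be analysed, since of the 15 looked up 0 were found among the matched transcripts.

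Library sizes were normalised with edgeR 4.0.16 (R 4.3.3) by the trimmed mean of M values (TMM), with factors of 1.02 for wild-type and 0.980 for p65-null. Genes with a mean of at least 1 CPM over both libraries were taken as measured, 12134 in all, with a median of 599 wild-type and 404 p65-null fragments. The log2 ratio is p65-null over wild-type normalised CPM. A count of 0 was set to a floor of 3 fragments in its library, so that the ratio is a bound. The floor equals 2.61 units of the wild-type column and 3.52 of the p65-null column. Intervals are exact Clopper-Pearson intervals at 95% for the share of fragments from 1 library; fragments were not tagged as molecules, so intervals and floors cover counting error only. For each gene list, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched in 20 bins of expression, as a description of these libraries. The interval of a list's median is an order-statistic interval over its members.

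The 41 gene lists (31 of pathways, 10 of cell types) and the rule for named genes were fixed before the data were examined. The text names Rela, the NF-kB family list, and the 15 genes higher and 15 lower with the largest interval end nearest 0, leaving out predicted genes. In each list it also names up to 3 members higher and 3 lower by the same measure. Some genes that these rules name are not reported here. Other members of the lists, Gm12610, Gm49890 and Gm12669, and the genes named only in the closing section, were named after their values were seen. How reads of overlapping or near-identical genes were assigned is not given in the sources used here, so such genes may share reads.

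The alternatives fixed beforehand were DESeq2 1.42.0 size factors, total counts, upper quartile factors and scaling to the ribosomal protein list. The deeper library was also thinned to the depth of the other, the 10 most abundant genes were left out, and the expression minimum was dropped or raised to 5 CPM. A prior count of 2, the interval end in place of the ratio, and the mean in place of a list's median completed the set. A loess correction (span 0.3) for GC content and then length of the matched GENCODE transcript, available for 11989 measured genes (98.8%), was added after seeing the data. So was the omission of the X and Y chromosomes.

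The ratio and interval step was tested on simulated counts for the p65-null against wild-type comparison over 12126 genes. Intervals held the true ratio for 97.0% of genes made 2-fold, 98.5% of genes made 4-fold and 96.9% of genes made 8-fold different, and for 95.3% of unchanged genes. The ratio passed 2-fold for 66.7% of the 2-fold genes, 100% of the 4- and 8-fold genes and 0.201% of the unchanged genes. A simulated list of 30 higher genes reached percentile 100 and 30 unchanged genes percentile 37.1. In a simulated GC trend over 11980 genes, the correction took the Spearman correlation from 0.904 to 0.0027. The trend was planted on GC content alone, which the correction itself fits. The fall therefore shows only that the step runs as written, not that it suits these libraries. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9, with 0.05 CPM added on the log scale of the expression plot.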

Results

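RNA sequencing was used to compare gene expression in 2 cultures of immortalised mouse embryonic fibroblasts (MEFs) of the C57BL/6 strain, 1 with intact p65 and 1 lacking it. p65, encoded by Rela, is a subunit of NF-kB, the transcription factor that drives many inflammatory and survival genes. The design asks which genes are expressed differently in the presence and in the absence of p65, and the labels name no stimulus. Each genotype had 1 library, so no difference has a replicate check and no p-value is given. The wild-type library held 20794476 fragments and the p65-null library 15441394 over 16881 transcripts. Ratios are p65-null over wild-type, and their 95% Clopper-Pearson intervals cover counting error in these 2 libraries only. Coordinates are those of GRCm38, the assembly also called mm10.

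Rela (transcript NM_009045, chromosome 19, 5637442 to 5648134) was 6.90-fold lower in the p65-null library (5.94 to 8.0), at 13.1 normalised CPM (fragment counts scaled to the library's size) against 90.4. The log2 ratio was -2.79 (-3.0 to -2.57), so 14.5% of the wild-type level remained (12.5% to 16.8%). Which exons the null allele lacks is not given in the sources used here, and reads were summed over the whole transcript. Among the 15 measured genes of the NF-kB family and its regulators, 4 were at least 2-fold lower in the p65-null library, 0 were at least 2-fold higher and 11 lay within 2-fold. Besides Rela, the lower ones were Tnfaip3, which encodes the NF-kB inhibitor A20, at 3.41-fold (2.95 to 3.95), Rel at 2.58-fold (1.53 to 4.30) and the kinase gene Chuk at 2.33-fold (2.06 to 2.64). Relb had a log2 ratio of 0.73, Nfkb1 of -0.18, Nfkb2 of 0.06, Nfkbia of 0.08, Nfkbib of 0.27, Nfkbie of -0.32, Nfkbiz of -0.59, Bcl3 of -0.11, Ikbkb of 0.12, Ikbkg of 0.07 and Tnip1 of 0.28. The median log2 ratio of the family was -0.11, at percentile 42.5 of random lists, and 0.01 under upper quartile scaling. After a correction for transcript GC content and length, the median was -0.27, Rel was at -0.52 and Chuk at -0.37, and Nfkb2, Nfkbia, Nfkbib and Tnip1 lay on the other side of 0, at -0.25, -0.13, -0.10 and -0.01.

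Across the transcriptome, 12134 genes had a mean of at least 1 CPM and were taken as measured. Of these, 1474 were at least 2-fold higher in the p65-null library and 1668 at least 2-fold lower, while 8992 (74.1%) lay within 2-fold. At least 4-fold differences were found for 527 genes higher and 426 genes lower, together 7.85% of the measured genes. The whole counting interval lay past 4-fold for 345 of the higher and 252 of the lower genes. The median log2 ratio was -0.03 and the interquartile range ran from -0.58 to 0.50. The log2 ratio followed transcript GC content across genes (Spearman 0.44), genes not being independent replicates, and the correction left 985 genes at least 2-fold lower and 1480 higher. The share of higher genes among those 2-fold apart was 46.9%, against 60.0% after that correction and 20.7% when the libraries were scaled to their ribosomal protein genes. Corrected log2 ratios are given below for named genes whose direction turned or that crossed 2-fold, either way, with the GC and length correction.

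**Figure D1:**
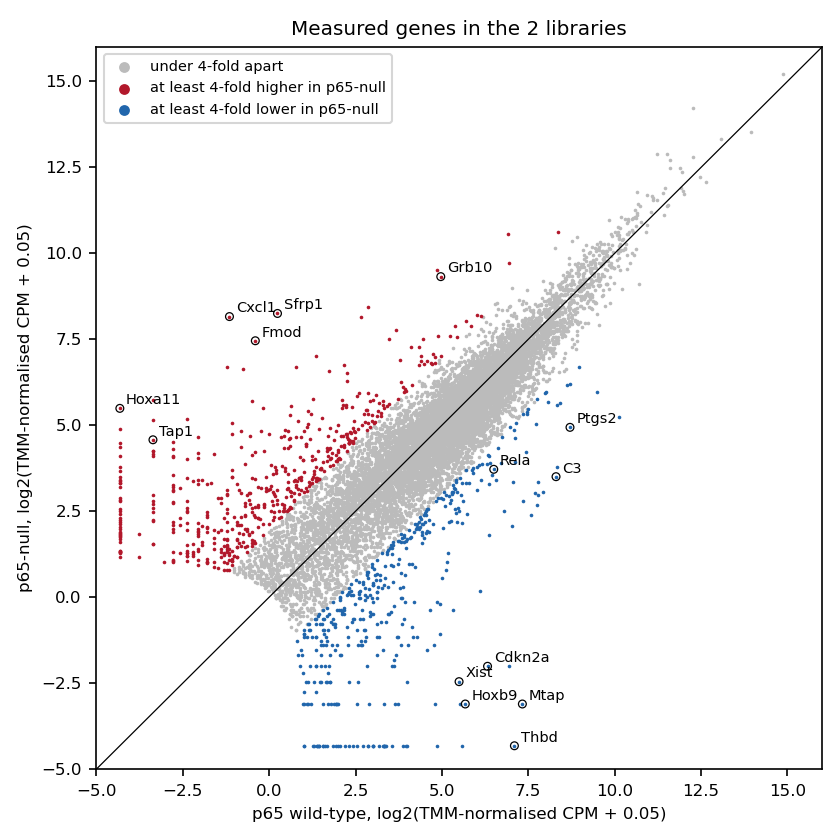
Each point is 1 of the 12134 measured genes, with log2 of TMM-normalised CPM plus 0.05 in the wild-type library on the horizontal axis and in the p65-null library on the vertical axis. Red points (527) were at least 4-fold higher and blue points (426) at least 4-fold lower in the p65-null library, the line marks equal levels, and the lowest row and column of points are genes with 0 fragments.

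The canonical target genes of NF-kB did not move one way. Of 43 measured targets, 12 were at least 2-fold lower in the p65-null library, 8 at least 2-fold higher and 23 within 2-fold. The lower ones included the acute-phase gene Saa3 at 32.6-fold (12.4 to 91.5), the complement component C3 at 27.9-fold (24 to 32.7), the iron-binding lipocalin Lcn2 at a log2 ratio of -4.16 (-4.73 to -3.63), and Ptgs2, which encodes cyclooxygenase-2, at 13.6-fold (12.4 to 15). Traf1 was 9.04-fold lower (4.60 to 20.3), and Nos2, Plau, Mmp3 and Birc2 had log2 ratios of -2.07, -1.88, -1.62 and -1.42, Birc2 being at -0.78 after the correction. The collagenase gene Mmp13 had 1 fragment in the p65-null library and a log2 ratio of -5.60 (-10.93 to -3.07). In the other direction, the neutrophil chemokine Cxcl1 (chromosome 5, 90891245 to 90893121) was 714-fold higher in the p65-null library (355 to 1475). Its level was 286 normalised CPM against 0.401 in the wild-type library, which rests on 8.5 fragments. Mmp9 had a log2 ratio of 3.64 (3.32 to 3.97) and Cx3cl1 was 3.90-fold higher (3.71 to 4.11). The median log2 ratio of the targets was -0.15 (95% interval -0.85 to 0.28), at percentile 21.5 among 10000 random lists matched on expression.

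Chemokine and cytokine genes were more often higher than lower in the p65-null library: 8 of 17 measured members were at least 2-fold higher and 1, Cxcl10, was at least 2-fold lower, at 2.02-fold (1.55 to 2.63), or -0.83 after the GC and length correction. Cxcl14 was 20.01-fold higher (9.36 to 51.1), Ccl5 had a log2 ratio of 2.75 (1.75 to 3.90), Cxcl5 of 1.69 and Il6 of 1.09. Of the more abundant members, Cxcl1 had a log2 ratio of 9.48, Cx3cl1 of 1.97, Cxcl12 of 0.62, Csf1 of -0.49 and Ccl2 of -0.60. The median was 0.72 (percentile 99.6), and it was -0.07 when only genes with a mean of at least 5 CPM were kept and 1.36 after the GC and length correction.

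Interferon-stimulated genes were largely higher without p65. Of 26 measured members, 22 were at least 2-fold higher in the p65-null library, 17 of them at least 4-fold, and 0 were at least 2-fold lower. The ubiquitin-like modifier Isg15 had 0 fragments in the wild-type library and was at least 41.6-fold higher, Ifi27 was 24.6-fold higher (19.9 to 30.5), and Ifit1, with 1 fragment in the wild-type library, had a log2 ratio of 7.12 (4.60 to 12.43). The signalling genes Irf7, Irf9 and Stat2 had log2 ratios of 4.47, 2.61 and 1.77. Irgm1 was the single member below 0, at 1.53-fold lower (1.41 to 1.66). The median log2 ratio was 3.44 (percentile 100), yet most members were of low abundance, with median levels of 0.637 normalised CPM in the wild-type and 7.2 in the p65-null library.

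Genes of MHC class I antigen presentation were also higher in the p65-null library, 7 of 16 at least 2-fold and 0 lower by that margin, with a median log2 ratio of 0.94 (percentile 99.99). The peptide transporter genes Tap1 and Tap2 on chromosome 17 had 1 and 2 fragments in the wild-type library and log2 ratios of 8.98 (6.49 to 14.29) and 7.50 (5.64 to 10.56). The immunoproteasome gene Psmb8 had a log2 ratio of 6.87 (4.36 to 12.20) and H2-K1 of 1.55 (1.22 to 1.89). H2-Q4, listed at 0 in the wild-type library, was at least 27.8-fold higher. B2m, the light chain shared by class I molecules, was at 0.01 (-0.06 to 0.09). Class I heavy chain genes are near-identical copies, and how reads were shared between them is not given in the sources used here.

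Apart from Cxcl1 and Tap1, the genes with the largest differences towards higher expression were mostly patterning and matrix genes. Secreted Wnt antagonists Sfrp1 (chromosome 8, 23411383 to 23449632) and Sfrp2 (chromosome 3, 83765750 to 83774314) were 269-fold (181 to 420) and 273-fold (138 to 633) higher in the p65-null library. The collagen-binding proteoglycan Fmod (chromosome 1, 134037254 to 134048280) was 248-fold higher (150 to 444). Hoxa11, Hoxd13, Hoxd11, Tbx5, Prss57 and the Y-linked Kdm5d had 0 fragments in the wild-type library and were at least 318-, 208-, 144-, 120-, 158- and 96.7-fold higher. Hoxa11os, Fstl3 and Hoxa10, with 1, 1 and 3 wild-type fragments, had log2 ratios of 10.13 (7.65 to 15.43), 9.56 (7.08 to 14.87) and 8.01 (6.46 to 10.29). Hoxa11 overlaps Hoxa11os and Fstl3 overlaps Prss57, and whether counting used strand is not given in the sources used here, so reads within these pairs cannot be assigned to 1 gene.

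The genes with the largest differences towards lower expression included the thrombomodulin gene Thbd (chromosome 2, 148404471 to 148408188), at 137 normalised CPM in the wild-type library and 0 fragments in the p65-null library, at least 691-fold lower. Prkar1b, a regulatory subunit gene of protein kinase A, was at least 240-fold lower and the transcription factor gene Pax8 at least 79.0-fold. The teneurin gene Tenm3 had 3 fragments left and a log2 ratio of -9.27 (-11.55 to -7.72), and the transcription factor gene Zic1 1 fragment and -9.44 (-14.74 to -6.96). A group of 4 neighbours on chromosome 4 was among the lowest: Wincr1, Mtap, Cdkn2a and Cdkn2b, between 89050307 and 89311032. Mtap, a methionine salvage enzyme gene, had 3407 fragments in the wild-type and 1 in the p65-null library, a log2 ratio of -11.25 (-16.55 to -8.77). Cdkn2a, which encodes the p16 and p19 tumour suppressors, had a log2 ratio of -8.65 (-10.93 to -7.11) with 3 fragments left, and Cdkn2b and Wincr1, with 0, were at least 146-fold and 59.6-fold lower. Cdkn2b lies within the non-coding gene Gm12610, which fell under the expression minimum, while the next measured genes, Gm49890 on one side and Gm12669 on the other, had log2 ratios of -1.82 and 0.13.

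**Figure D2:**
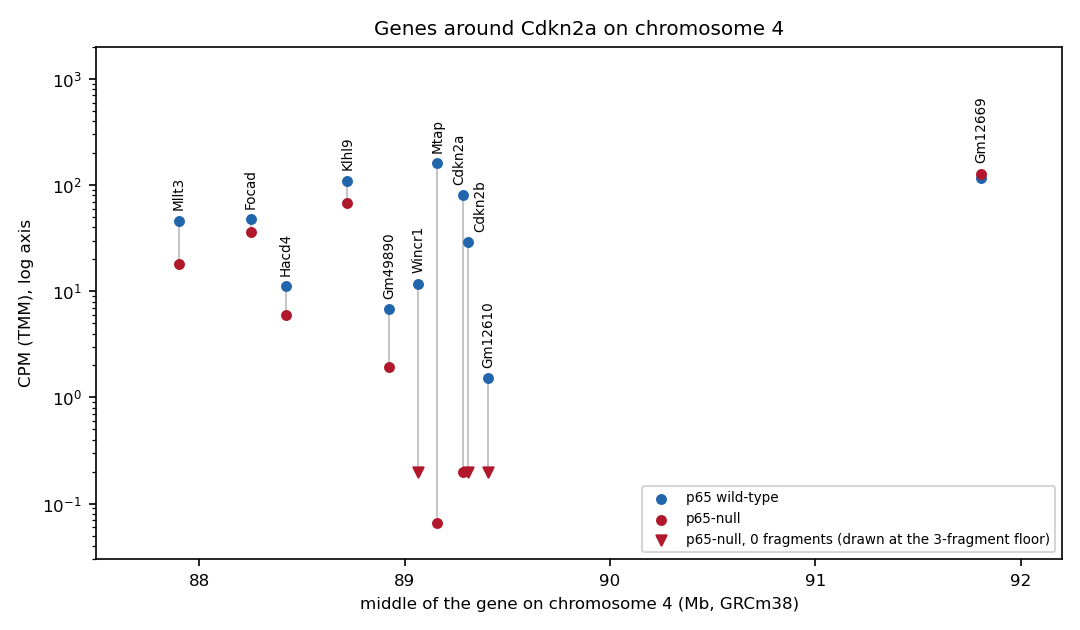
TMM-normalised CPM on a log axis for genes of chromosome 4 around Cdkn2a, placed at the middle of each gene, with blue for the wild-type and red for the p65-null library and triangles where the p65-null library had 0 fragments, drawn at the level of 3 fragments. Wincr1, Mtap, Gm12610, Cdkn2a and Cdkn2b had at most 3 fragments in the p65-null library, and their neighbours on both sides had more.

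Hox genes, which carry positional identity along the body axis and the limbs, split into opposite groups. Of 22 measured members, 12 were at least 4-fold lower in the p65-null library, 9 at least 4-fold higher and 1, Hoxa7, lay within 2-fold at 0.38. The lower members included Hoxa2 to Hoxa5 and all 7 measured genes of the Hoxb cluster, among them Hoxb9 with a log2 ratio of -9.59 (-14.90 to -7.11) and Hoxb7, Hoxb2 and Hoxb3 at least 80.4-, 73.9- and 51.6-fold lower. The higher members were Hoxa9, Hoxa10, Hoxa11 and Hoxa13 and the Hoxd genes from Hoxd8 to Hoxd13, the 5' ends of their clusters. Hoxa9 had a log2 ratio of 4.72 (3.95 to 5.61), and Hoxa13, Hoxd8, Hoxd10 and Hoxd9 had 0 wild-type fragments and log2 ratios of at least 6.30, 6.14, 5.59 and 5.31. The median of the list was -2.43 and its mean -0.03, since the members went both ways. Of the 39 Hox genes looked up, 29 were found among the matched transcripts and 22 were measured. Genes of the Hoxc cluster from Hoxc4 to Hoxc12 were not analysed here.

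**Figure D3:**
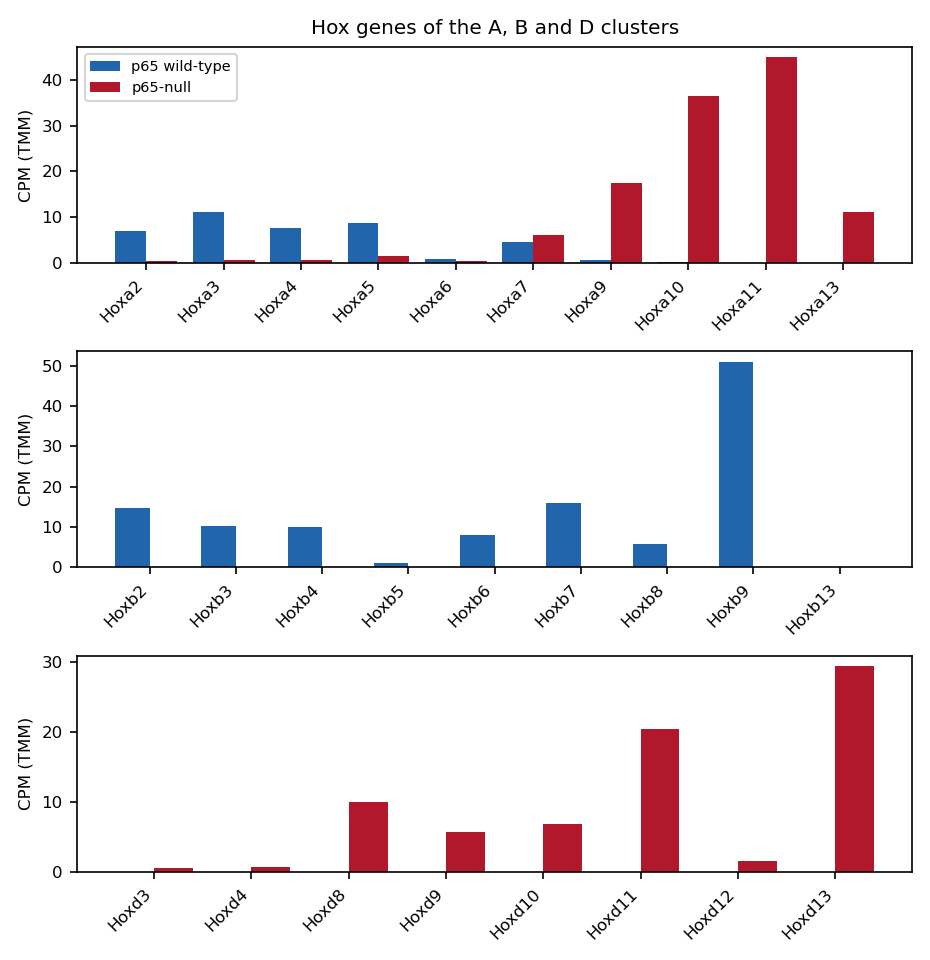
Bars give TMM-normalised CPM of Hox genes of the A, B and D clusters, including those under the expression minimum, with blue for the wild-type and red for the p65-null library and 1 library per bar. Hoxa2 to Hoxa5 and the Hoxb genes from Hoxb2 to Hoxb9 were higher in the wild-type library, and Hoxa9 to Hoxa13 and the Hoxd genes were higher in the p65-null library.

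Other developmental transcription factors also lay on opposite sides. Of 41 measured mesenchymal transcription factors, 11 were at least 2-fold higher and 8 at least 2-fold lower in the p65-null library. Gata4 and Msx1, with 1 wild-type fragment each, had log2 ratios of 8.64 (6.16 to 13.95) and 8.51 (6.02 to 13.82), and En1 of 5.77 (5.05 to 6.49). Pax9 was 6.18-fold lower (4.18 to 9.52) and Foxf1 3.59-fold lower (3.19 to 4.06). The median was -0.05 and the mean 1.02, and the median was 0.06 under upper quartile scaling, 0.33 with no expression minimum and 0.19 after the GC and length correction.

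The libraries differed in sex-linked genes. Xist, the non-coding RNA of the inactive X chromosome, had 956 fragments in the wild-type and 2 in the p65-null library, a log2 ratio of -8.41 (-11.46 to -6.56), and Tsix, which overlaps it, was at least 24.9-fold lower. The Y-linked genes Kdm5d, Eif2s3y and Ddx3y had 0 wild-type fragments and were at least 96.7-, 64.4- and 49.7-fold higher in the p65-null library. Uty, with 1 wild-type fragment, had a log2 ratio of 6.61 (4.09 to 11.94). The sex chromosomes held 4.51% of the genes at least 4-fold apart and 3.26% of all measured genes.

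Extracellular matrix genes were largely higher in the p65-null library. Among 31 measured genes of fibrillar collagens and associated matrix, 12 were at least 2-fold higher and 3 lower, with a median log2 ratio of 0.79 (percentile 100). Col1a1, Col1a2 and Col3a1, the main fibrillar collagen chains, had log2 ratios of 1.11 (0.92 after the GC and length correction), 1.38 and 1.56, and the microfibril gene Mfap5 of 6.25 (4.41 to 8.28). Mfap4 was at 6.59 (4.71 to 9.65), and the proteoglycan Lum was 23.3-fold higher (9.57 to 73.5). The lower members were Thbs2 at 5.62-fold (5.28 to 5.98), Col11a1 at 3.37-fold (3.05 to 3.72) and Col8a1 at 3.35-fold (3.12 to 3.60). Basement membrane genes had 9 of 18 members at least 2-fold higher and 0 lower by that margin, with a median of 1.04 (percentile 100). Lama4 was 8.36-fold higher (7.56 to 9.23), and the type IV collagen chains Col4a1 and Col4a2, which lie head to head on chromosome 8, were 3.71-fold (3.60 to 3.82) and 3.93-fold (3.76 to 4.11) higher. Lama2 and Lamb1 went the other way, with log2 ratios of -0.86 and -0.61.

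Matrix proteases and their inhibitors were divided, with 7 of 22 at least 2-fold higher and 7 at least 2-fold lower and a median of 0.49 (percentile 99.9). Cathepsin K (Ctsk) had a log2 ratio of 6.27 (4.70 to 8.56), and the protease inhibitor Serpine2 was 6.89-fold higher (5.85 to 8.11). Plau, which encodes urokinase, was 3.69-fold lower (3.31 to 4.12). Contractile genes were lower on the whole: 6 of 22 were at least 2-fold lower and 1, Lmod1, higher, with a median of -0.41 (percentile 0.31). The smooth muscle genes Actg2 and Cnn1 were 33.6-fold (27.3 to 41.3) and 25.4-fold (21.2 to 30.6) lower and Ankrd1 21.7-fold lower (18.4 to 25.6), whereas Acta2 had a log2 ratio of 0.45 and Cnn2 of 0.17, or -0.04 after the GC and length correction.

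Among signalling genes, Wnt pathway members were often higher in the p65-null library, 11 of 24 at least 2-fold and 3 lower, with a median of 0.63 (percentile 99.6). Beyond the Sfrp genes, the ligand gene Wnt10b had a log2 ratio of 7.48 (5.62 to 10.54) and Axin2, a common target of the pathway, of 3.85 (3.20 to 4.57). Wnt5a was 3.85-fold lower (3.34 to 4.46), Ror1, a receptor for it, 2.89-fold (1.76 to 4.98) and Nkd2 2.64-fold (1.39 to 4.99). Growth factors and their receptors were more often lower, 14 of 33 at least 2-fold against 6 higher, with a median of -0.41 (percentile 1.44), or -0.16 after the correction. Hgf had 2 fragments in the p65-null library and a log2 ratio of -6.90 (-9.96 to -5.04), Fgf10 was 12-fold lower (7.27 to 20.02) and Hbegf 9.0-fold lower (7.66 to 10.6). The insulin-like growth factor gene Igf2 was 78.1-fold higher (40.8 to 172), Igfbp4 25.4-fold higher (23.4 to 27.6) and Igfbp3 had a log2 ratio of 6.13 (4.24 to 9.20). In the TGF-beta and BMP pathway, 8 of 26 members were at least 2-fold lower and 3 higher, with a median of -0.27 (percentile 9.59), or -0.06 after the correction. Bmpr1b was 7.41-fold lower (4.22 to 13.2) and Skil 4.63-fold (4.06 to 5.28), while Tgfb3 was 3.65-fold higher (3.41 to 3.91), Tgfb2 3.09-fold (2.53 to 3.78) and Tgfbi 3.01-fold (2.82 to 3.21).

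Target genes of p53, the tumour suppressor, were higher in the p65-null library, 9 of 26 at least 2-fold and 3 lower, with a median of 0.79 (percentile 100). The cell cycle inhibitor Cdkn1a was 7.47-fold higher (5.84 to 9.53), Dcxr 19.97-fold (14.8 to 27.7) and Psrc1 11.1-fold (8.94 to 13.96), and Rrm2b, Pmaip1 and Gdf15 were 4.13-fold (2.73 to 6.25), 4.12-fold (2.01 to 9.52) and 2.75-fold (1.34 to 5.74) lower, Rrm2b being at -0.91 after the GC and length correction. The gene for p53 itself, Trp53, had a log2 ratio of -0.13. Among 13 immortalisation loci and cell cycle inhibitors, 2 were at least 2-fold higher and 3 lower, with a median of -0.13 that became 0.07 after the correction. Besides Cdkn2a and Cdkn2b, the polycomb gene Bmi1 was 2.63-fold lower (2.30 to 3.02), at -0.41 after the correction, and the telomerase gene Tert was 2.77-fold higher (1.85 to 4.09) and Cdkn2c 1.33-fold (1.21 to 1.46).

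Apoptosis regulators had 3 of 33 members at least 2-fold higher and 5 lower, and their median was 0.11 (percentile 81.7), or -0.36 with the libraries scaled to their ribosomal protein genes. After the GC and length correction, 7 were higher and 3 lower, with a median of 0.24. The pro-apoptotic Bmf was 12.6-fold higher (7.83 to 21.5), and the caspase gene Casp9 was 2.97-fold higher (2.35 to 3.78). The survival genes Bcl2 and Xiap were 2.92-fold (2.41 to 3.57) and 3.22-fold (2.73 to 3.83) lower, at -1.08 and -0.50 after the correction. Cell cycle genes differed little, with 34 of 36 within 2-fold and a median of -0.05, which was 0.07 under upper quartile scaling and 0.12 after the correction. Mcm5 was 1.82-fold higher (1.77 to 1.88), Ccnb2 1.75-fold (1.61 to 1.89) and Bub1b 1.42-fold (1.35 to 1.49), and Kif11 was 1.57-fold lower (1.47 to 1.69), or 0.16 after the correction. Ccne2 and Bub1 were 2.76-fold (2.31 to 3.31) and 2.14-fold (1.93 to 2.37) lower, but at 0.12 and -0.21 after the correction.

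DNA repair genes also lay mainly within 2-fold, 26 of 30, with a median of 0.00 that was -0.01 with DESeq2 size factors, -0.05 with total counts and -0.47 with the ribosomal scaling. The largest difference was that of Mgmt, which encodes a repair enzyme for alkylated guanine, with a log2 ratio of 7.72 (5.85 to 10.77). Xrcc5 was 1.57-fold higher (1.42 to 1.74) and Xrcc1 1.39-fold (1.28 to 1.52). Atm, Atr and Brca2 were 2.60-fold (2.34 to 2.90), 2.22-fold (1.88 to 2.62) and 2.13-fold (1.85 to 2.47) lower, at -0.54, -0.09 and -0.17 after the correction.

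Antioxidant genes under NRF2 had 6 of 26 members at least 2-fold higher and 2 lower, and their median was 0.16 (percentile 87.8), or -0.31 with the ribosomal scaling. Glutathione transferase genes led the higher ones, Gstt1 at 8.77-fold (7.14 to 10.8), Gstm2 at 6.96-fold (5.85 to 8.28) and Gstm1 at 4.98-fold (4.50 to 5.51). The extracellular superoxide dismutase Sod3 was 3.14-fold lower (2.41 to 4.16), and Gclc and Gclm, the subunits of glutamate-cysteine ligase, 2.07-fold (1.80 to 2.38) and 1.75-fold (1.55 to 1.99), at -0.82 and 0.04 after the GC and length correction. For ATF4 and unfolded protein response genes, 4 of 24 were at least 2-fold higher and 0 lower, with a median of 0.15 (percentile 78.6), or -0.33 with the ribosomal scaling and 0.27 after the correction. Sesn2 was 3.96-fold higher (3.41 to 4.60), Trib3 3.02-fold (2.42 to 3.76) and Chac1 2.84-fold (2.34 to 3.47), while Mthfd2, Hsp90b1 and Psat1 had log2 ratios of -0.27, -0.25 and -0.09, and of -0.27, 0.27 and 0.03 after the correction.

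Central metabolism was closer between the libraries. In glycolysis and hypoxia, 22 of 24 genes lay within 2-fold, with a median of -0.10 that was 0.01 under upper quartile scaling and -0.34 after the GC and length correction. Vegfa was 3.96-fold lower (3.64 to 4.30) and Ldhb 2.32-fold higher (2.11 to 2.56), or 0.98 after the correction, while Pfkm and Ndrg1 had log2 ratios of 0.97 and 0.84 and Hk2 and Pgk1 of -0.78 and -0.48. All 30 measured genes of oxidative phosphorylation lay within 2-fold, with a median of 0.19 (percentile 97.7), or -0.28 with the ribosomal scaling. Sdhc was at 0.95, or 1.09 after the correction, Ndufb8 at 0.76 and Cox4i1 at 0.73, against Cycs at -0.56, Tfam at -0.53 and Ndufa4 at -0.28, which were at 0.34, -0.04 and 0.04 after the correction. Of 28 genes of sterol and fatty acid synthesis, 23 lay within 2-fold and 5 were lower, with a median of -0.36 (percentile 2.75), inside the central 95% of random lists, or -0.27 after the correction. The sterol transporter gene Stard4 was 3.65-fold lower (3.04 to 4.37) and Insig1 2.47-fold (2.21 to 2.77). Fdps, Srebf1 and Scd2 were at 0.44, 0.21 and 0.20, Srebf1 being at -0.02 after the correction.

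Ribosomal protein genes were shifted together, 39 of 43 higher in the p65-null library and 1, Rpl37a, by at least 2-fold at 2.03-fold (1.98 to 2.08), with a median of 0.47 (percentile 100), or 0.24 after the GC and length correction. Rps7 and Rps19 were at 0.81 and 0.78, and Rpl6, Rpl5 and Rpl30 at -0.48, -0.26 and -0.20. After the correction Rps19 was at 0.27 and Rpl5 at 0.34. These genes have many processed pseudogenes, and how the counting treated shared reads is not given in the sources used here. Of 25 replication-dependent histone genes, also near-identical copies, all lay within 2-fold, with a median of 0.39 (percentile 99.3) that was -0.08 with the ribosomal scaling and 0.04 after the correction. H1f2, H1f3 and H4c1 were at 0.76, 0.75 and 0.61 and H1f1 at -0.28. H1f3 alone passed 2-fold after the correction, at 1.92. The GENCODE transcript matched to H1f3 has 7425 bases, more than the gene spans (chromosome 13, 23555032 to 23555807). Its corrected value is therefore unreliable. H1f2 and H4c1 were also matched to transcripts longer than the genes, of 1560 and 539 bases. The corrected median of the histone list rests in part on such matches. Reference genes had 24 of 25 members within 2-fold and a median of -0.36 (percentile 1.0). The transferrin receptor gene Tfrc was 5.25-fold lower (4.87 to 5.67), Ywhaz and Reep5 were at -0.83 and -0.67, and Rpl13a, Ppia and Psmb4 were at 0.85, 0.56 and 0.47.

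Immediate early genes were divided, with 4 of 25 at least 2-fold higher and 7 lower and a median of -0.07, which was 0.04 under upper quartile scaling, 0.15 with the deeper library thinned and -0.21 after the GC and length correction. Btg2, Egr2 and Egr1 were 5.22-fold (4.22 to 6.45), 3.89-fold (2.70 to 5.71) and 2.78-fold (2.41 to 3.22) higher. The MAP kinase phosphatases Dusp2, Dusp5 and Dusp6 were 6.63-fold (3.81 to 12.5), 3.86-fold (3.27 to 4.58) and 3.48-fold (3.09 to 3.92) lower. Among imprinted genes, 6 of 23 were at least 2-fold higher and 2 lower, with a median of 0.43 (percentile 98.6) that was -0.04 with the ribosomal scaling. With Igf2, the neighbouring non-coding gene H19 was 10.8-fold higher (7.87 to 14.7), and Grb10 on chromosome 11 was 20.5-fold higher (18.9 to 22.2). Kcnq1ot1 and Peg10 were 3.65-fold (3.01 to 4.46) and 2.74-fold (2.49 to 3.02) lower, and Impact was at -0.86. After the GC and length correction, Kcnq1ot1 and Impact were at -0.27 and -0.10. The transcript matched to Kcnq1ot1 has 93092 bases, more than the gene spans (chromosome 7, 143213111 to 143296547). The corrected value of Kcnq1ot1 is therefore unreliable.

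**Figure D4:**
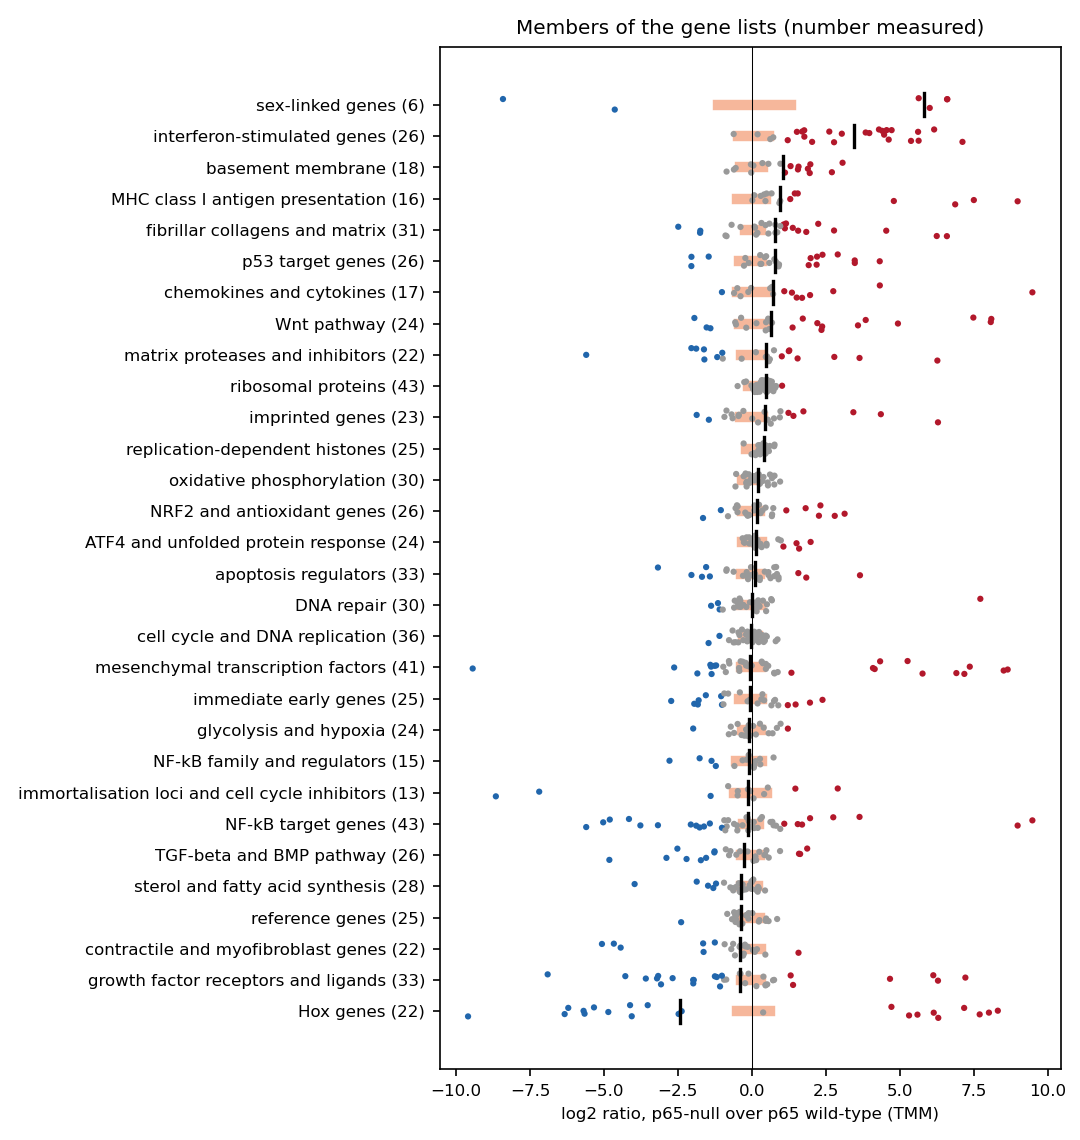
Points are the log2 ratios, p65-null over wild-type, of the measured members of each pathway list, with their number in brackets, red at least 2-fold higher, blue at least 2-fold lower and grey within 2-fold. The black tick is the list's median and the pale bar holds the central 95% of medians of random lists matched on expression; interferon-stimulated genes had a median of 3.44 and Hox genes of -2.43.

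Markers of fibroblasts had a median level of 153 normalised CPM in the wild-type and 191 in the p65-null library, and 5 of 11 were at least 2-fold higher and 1 lower in the p65-null library, with a median of 0.71 (percentile 99.98). S100a4 was 12.5-fold higher (11.98 to 13) and Thy1 8.59-fold lower (7.26 to 10.2), while Dcn and Pdgfrb were at -0.69 and -0.41. Of markers of other cell types, 3 of macrophages, 3 of endothelium, 2 of epithelium and 3 of skeletal muscle were measured. Their medians were -0.97, -0.76, 1.03 and -1.95. Cd14 was 3.88-fold lower (2.96 to 5.07), Csf1r 1.96-fold lower (1.09 to 3.73), or -1.11 after the GC and length correction, and Cd68 2.97-fold higher (1.90 to 4.83). The endothelial genes Eng, Kdr and Flt1 were at -1.09, -0.76 and -0.35, and the keratin gene Krt19 was 2.90-fold higher (2.55 to 3.30). Tnnt2 was 33.9-fold lower (19.7 to 64.0) and Acta1 3.87-fold lower (2.14 to 7.68).

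Smooth muscle and pericyte markers went both ways, with 2 of 7 at least 2-fold higher and 3 lower; the median of 0.29 stood against a mean of -0.60 and was -0.18 with the ribosomal scaling, -0.72 with a mean of at least 5 CPM and 0.15 after the GC and length correction. Notch3 was 28.4-fold higher (18.2 to 47.1), Rgs5 3.27-fold (1.87 to 5.75), and Mcam 3.31-fold lower (2.89 to 3.80). Of 5 adipocyte markers, 2 were at least 2-fold higher and 1 lower, with a median of 0.31, or -0.17 with the ribosomal scaling. Cebpa was 4.18-fold (3.04 to 5.81) and Plin4 3.54-fold (2.23 to 5.55) higher, Fabp4 2.10-fold lower (1.47 to 3.07), and Cebpb at 0.22, the last 2 being at -0.27 and -0.34 after the GC and length correction. Cartilage and bone markers had 1 of 8 members at least 2-fold higher and 3 lower, with a median of -0.49, or -0.13 after the correction. The cartilage proteoglycan Acan was 42.7-fold lower (18.09 to 132), Spp1 11.4-fold (10.7 to 12.2) and Alpl 4.49-fold (3.33 to 6.19), whereas Col2a1 was 4.15-fold higher (3.80 to 4.54) and Col11a2 1.98-fold (1.07 to 3.67). Neural and glial markers had 2 of 6 higher and 3 lower, with a median of -0.90 and a mean of 0.27. Nes, Sox11 and Tubb3 were 6.64-fold (6.16 to 7.18), 5.61-fold (4.88 to 6.48) and 2.88-fold (2.58 to 3.22) lower and Stmn2 3.98-fold higher (2.86 to 5.61). The transcription factor gene Sox2, also among the 2 measured pluripotency markers (median 4.02), had a log2 ratio of 6.65 (4.78 to 9.72), and Nanog was 2.62-fold higher (1.47 to 4.71).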

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

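The GC and length correction and the omission of the sex chromosomes were chosen after seeing the data, and the other alternatives were fixed before. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out. The 4 gene counts, the Rela ratio and the NF-kB target median gave 67 values under the alternatives, of which 52 were unchanged and 15 were not, where a count within 1.5-fold and a ratio or median within its 95% interval was taken as unchanged. For genes at least 2-fold higher (1474), the count was 856 with the libraries scaled to the ribosomal protein list, 2471 with no expression minimum, 922 with a mean of at least 5 CPM and 965 by the interval end. For genes at least 2-fold lower (1668), it was 3289 with the ribosomal scaling, 1103 by the interval end and 985 after the GC and length correction. For genes at least 4-fold higher (527), it was 991 with no minimum, 271 at 5 CPM and 345 by the interval end. For genes at least 4-fold lower (426), it was 790 with the ribosomal scaling, 227 at 5 CPM and 252 by the interval end. The Rela log2 ratio (-2.79) was -3.26 with the ribosomal scaling and -3.13 after the correction. The stricter minimum tested 10172 genes and no minimum 16881, which by construction lowers and raises the counts. The interval end lies nearer 0 than the ratio, so by construction it lowers them. The cause of the shifts after the GC and length correction was not tested. The ribosomal scaling moved every log2 ratio, and so the median of all genes, by -0.47, and its shifts follow from that offset. The upper quartile factors moved the median by 0.12. The NF-kB target median (-0.15) lay between -0.62 with the ribosomal scaling and -0.03 with upper quartile factors, all within its interval of -0.85 to 0.28. Among 4-fold genes, 55.3% were higher, against 32.0% with the ribosomal scaling and 61.2% after the correction, which shared 743 genes with the reported set, of the 939 of its 953 genes that could be corrected. For other named genes and lists, 1823 of 2196 values were unchanged, 372 moved past the interval and 1, Ccne2, at least 2-fold apart as reported, changed sign, from -1.47 to 0.12 after the correction. In all 59 of these values changed sign: 28 list medians, of which 9 with the ribosomal scaling, and 31 values of single genes, of which 15 after the correction and 14 with the ribosomal scaling.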

Other observations

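Beyond the lists, 2 abundant non-coding RNAs were higher in the p65-null library. Rpph1, the RNA of ribonuclease P, had a log2 ratio of 1.95 (1.94 to 1.96), and Rmrp, the RNA of the related ribonuclease MRP, of 1.64 (1.63 to 1.66). After the GC and length correction they were at 1.34 and 1.13. Transcript NR_046233, which was not matched to a gene name, had a log2 ratio of 0.37 (0.36 to 0.37). These RNAs were singled out after their values were seen.

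Neighbouring genes often differed together. There were 11 runs of at least 4 adjacent measured genes that were all at least 4-fold apart in the same direction, against at most 2 in 1000 shuffles of the ratios over gene positions. Besides the Hox clusters, the Y chromosome and the Cdkn2a neighbourhood, the runs higher in the p65-null library were Ugt1a10, Ugt1a9, Ugt1a7c and Ugt1a6b on chromosome 1, Prelp, Fmod, Btg2 and Chil1 on chromosome 1, Serpina3g, Serpina3h, Serpina3i and Gsc on chromosome 12, and Trim12a, Trim12c, Trim30a and Trim30d on chromosome 7. The zinc finger genes Zfp51, Zfp53, Zfp52 and Zfp948 on chromosome 17 were lower. Several of these are families of near-identical or overlapping genes, which can share reads. Whole chromosomes also differed, with median log2 ratios of -0.50 for chromosome 18, -0.45 for X and -0.44 for chromosome 5 against 0.28 for chromosome 7 and -0.03 for all measured genes. After the GC and length correction these 4 chromosomes were at -0.32, -0.14, -0.38 and 0.16, and the highest were chromosome 12 at 0.42 and chromosome 1 at 0.35, the Y chromosome with its 4 genes aside.

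The tests that follow were chosen after the results were seen, the GC and length correction among them; for interferon-stimulated genes, the bound was set before the corrected median was seen. The 2 cultures differed in ways that need not follow from the loss of p65. From Wincr1 to Cdkn2b on chromosome 4, 179 fragments were expected for Wincr1 and 0 seen, too many for shallow sequencing to hide. A run of 4 neighbours as low arose in 0 of 10000 shuffles. The shuffles took their threshold from these same 4 genes and treated neighbours as independent, although neighbours often differed together elsewhere. They therefore add no separate evidence about this segment. Deletion and silencing of this segment cannot be told apart: all 5 genes in it expected to give at least 10 fragments had at most 3, but the segment was drawn around genes near 0, and no DNA was analysed here. Of the Y-linked genes, 4 of 4 were above the floor in the p65-null library alone, while Xist was lower there, which is consistent with lines derived from embryos of different sex. Of 22 Hox genes, 21 were at least 4-fold apart, 9 higher and 12 lower, and whether this reflects the body region or clone of origin or the genotype cannot be told apart, since each genotype is 1 line.

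Rela kept 14.5% of its wild-type level in the p65-null library. Cells or reads of the sequenced wild-type culture in that library could leave such a remainder, but they would leave at least as much of every other gene. The intervals of 121 genes lay wholly below that of Rela, Xist at 0.293% (0.0354% to 1.06%) and Mtap at 0.0411% (0.00104% to 0.229%) of the wild-type level among them, which argues against that source as the whole cause. That comparison covers only the wild-type culture sequenced here, not other cells with intact p65. A residual transcript of the disrupted allele remains open, since reads per exon were not analysed here.

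Genes with low GC content tended to be lower in the p65-null library. In the fifth of genes with the lowest GC content, 850 (35.4%) were at least 2-fold lower, against 5.30% in the fifth with the highest, and the Spearman correlation with length was -0.22. Of 1222 genes 2- to 4-fold lower, 448 (36.66%) stayed at least 2-fold lower after the correction, so for most of these a library-wide trend, technical or not, may account for the call. Of 418 genes at least 4-fold lower, 288 (68.9%) stayed at least 4-fold lower, which leaves the share of the trend in this group open. Interferon-stimulated genes had a median log2 ratio of 3.44 before and 3.316 after the correction, with 22 of 26 at least 2-fold higher each time, so the trend does not account for them, and whether loss of p65 or another difference between the lines does was not tested.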
